A study of Arabidopsis thaliana with 18 samples.

How the data were processed

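RNA sequencing libraries were analysed from 18 samples of 3-day-old Arabidopsis thaliana seedlings grown in darkness at 21 °C, with 3 libraries in each of 6 groups. The groups combined 3 genotypes with growth without sucrose or with 1% sucrose. Per the labels' protocols, total RNA was extracted with the NucleoSpin RNA kit. The library kit, the strand of the reads, the read aligner, the counting program and their settings are not given in the sources used here. Reads were mapped to the TAIR 10 assembly, per the submitters' processing notes. Replicates were not described as separate cultures, so the p-values measure the spread between these samples.

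One table per library was deposited, with 32833 genes each. Per the file headers, the tables hold counts of total, unique, exon and intron reads per gene, where total reads include reads with more than 1 match. The authors also gave RPKM values, and their "Expression value" column equalled RPKM in all 18 files. TPM values, scaled by the authors to the same sum in each library, were deposited in a further column. Per the file headers, each gene also has the fraction of its exon reads that were unique and the fraction of its reads that fell in introns. Total gene reads were used here, and the RPKM and TPM columns entered no test. Gene positions were compared with the reference annotation, in which 32532 of the 32548 nuclear genes found in both had the same start and end. Because the strand was not stated, reads of overlapping antisense genes cannot be told apart, and reads of near-identical paralogs are shared uncertainly.

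The libraries held 27362791 to 41942516 total gene reads. The 18 pairs of replicates within groups differed by 5.28 to 102.94 chi square per degree of freedom, and no pair was identical. Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and DESeq2 1.42.0 for the other tests. The edgeR filter for low counts kept 21903 genes, of which 21743 were nuclear. Library sizes were scaled with trimmed means of M values (TMM), and 1 model of the 6 group means was fitted to all 18 libraries with robust quasi-likelihood dispersion, leaving 12 residual degrees of freedom. The common squared biological coefficient of variation was 0.0289. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within a comparison. Levels are CPM, counts scaled to the normalized library size, given as mean ± SD of n = 3. Changes are log2 ratios ± SE, with the SE taken as the log2 ratio divided by the square root of the F statistic.

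The 9 comparisons were sucrose against no sucrose within each genotype, each mutant line against Col-0 on each medium, and the difference of the sucrose response of each line from that of Col-0. Per comparison, 23 gene lists with 502 members were tested with camera in limma, on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. All 502 members were in the files, 498 by name and 4 under another name. Lists with fewer than 5 tested members were to be left out, and none was. The same tests were run with the correlation estimated from the data, and with the calls of a list's members adjusted over the list alone.

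Genes were named by a fixed rule. GNC and GNL came first. In each comparison other than the differences of responses, the 6 genes with the largest increase and the 6 with the largest decrease were named, among called nuclear genes with a mean of at least 2 CPM and no overlap between the groups. For 3 libraries against 3, chance alone gives 10% of genes without overlap. In each difference of responses, the 10 genes with the smallest adjusted p were named, and up to 4 called members of each list were named in each comparison. Where a group had no reads of a gene, the ratio was bounded with 3 counts over the group. Where it had 1 to 3 reads, the ratio of the pooled levels is given with an exact (Clopper-Pearson) 95% interval. Intron shares have Wilson 95% intervals. Intervals and bounds cover counting error only, since PCR copies of a molecule are counted as separate reads.

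Groups, comparisons, tests, lists, the naming rule and most alternatives were set before the data were examined. The alternatives were DESeq2's normalization (RLE), no filter on low counts, the DESeq2 Wald test, a fit of only the compared groups, a block for the replicate number, unique reads, nuclear genes only, each library left out in turn and, for the lists, the estimated correlation. Exon reads, and counts without the 15 rRNA genes, were added after seeing the data. Where a left-out library left a group with 2 libraries, the spread was pooled over the groups.

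Whether the replicate numbers pair samples across groups was checked by correlating, over genes, the deviations of same-numbered libraries from their group means. For GNLox against Col-0 without sucrose the 3 correlations were 0.366, 0.102 and 0.225, the second below the 0.151 of a differently numbered library. They were 0.182, 0.04 and 0.057 for sucrose in Col-0, and -0.051, -0.172 and -0.355 for gnc gnl against Col-0 with sucrose. The other comparisons were negative or of mixed sign, so the numbers did not pair samples throughout. The result with a replicate block is given beside GNLox against Col-0 without sucrose. The pipeline was tested on simulated data in which 200 of the 21903 genes changed. These were drawn from nuclear genes outside the lists with a mean of at least 2 CPM over the 18 libraries. Recovery of genes below that level was not simulated. At a 2-fold change, 74.6% to 85.1% of the changed genes were recovered in the comparisons of 2 groups, and 64.2% and 67.2% in the differences of responses, with 3 to 9 false calls. Each simulated shift of a list was called, and 0 other lists were called by camera. Counts of each gene were drawn independently of the other genes. Neither these results nor the 3 to 9 false calls therefore show how the tests behave where genes vary together. For sucrose in Col-0 the estimated correlation was 0.633 for ribosomal protein genes and 0.936 for photosystem genes.

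Overlaps of calls were compared with the product of the counts divided by the number of genes. Because gnc gnl and GNLox were compared with the same Col-0 libraries, their overlaps were also compared with 20 simulations of unchanged groups against shared controls. Neighbouring nuclear genes with a mean of at least 2 CPM that shifted by more than 0.3 on the log2 scale in both media were collected into runs and compared with 1000 shuffled gene orders. Gene families were formed from symbols with a shared stem and at least 8 tested members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.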

Results

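Messenger RNA levels were measured by RNA sequencing in dark-grown seedlings of 3 genotypes, each raised without and with 1% sucrose. Col-0 was the reference, gnc gnl was a double mutant of the B-GATA transcription factor genes GNC and GNL, and GNLox overexpressed GNL. B-GATA factors of this type are known as regulators of chlorophyll synthesis, greening and germination. Each of the 6 groups had 3 libraries. Total gene reads per library were 30508391 to 41942516 in Col-0, 27362791 to 41342111 in gnc gnl and 32368268 to 39143241 in GNLox. The series compares the 3 genotypes in darkness at both sugar conditions, and the comparisons ask which genes respond to sucrose, which depend on the GATA genes, and whether the response to sucrose differs between genotypes. A gene or list is said to have risen, fallen or changed where its adjusted p was under 0.05.

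GNL (AT4G26150, also known as CGA1 and GATA22) was the gene with the largest difference in GNLox. Its level was 13.5 ± 7.99 CPM in Col-0 and 5870 ± 640 CPM in GNLox without sucrose, a log2 difference of 8.76 ± 0.53 (edgeR adjusted p = 6.19e-07). With sucrose it was 1.9 ± 0.81 CPM in Col-0 and 4190 ± 1240 CPM in GNLox, a log2 difference of 11.08 ± 0.59 (edgeR adjusted p = 8.99e-08). In gnc gnl, reads of GNL remained, at 9.61 ± 2.17 CPM without sucrose and 4.12 ± 1.1 CPM with sucrose, and neither level differed from Col-0 (edgeR adjusted p = 0.526 and 0.252). The read counts of GNL therefore do not check the mutant label. GNC (AT5G56860) was lower in gnc gnl without sucrose, at 9 ± 0.43 against 27.4 ± 9.18 CPM (log2 -1.61 ± 0.29, edgeR adjusted p = 0.0195). With sucrose GNC was at 5.99 ± 0.63 against 14.4 ± 3.65 CPM, which did not pass (edgeR adjusted p = 0.112). In GNLox, GNC was lower than in Col-0 with sucrose, at 6.03 ± 2.39 CPM (log2 -1.25 ± 0.29, edgeR adjusted p = 0.00818), and was 16.5 ± 4.25 CPM without it (edgeR adjusted p = 0.0945). The call of GNC in gnc gnl without sucrose was lost in 4 of the 6 fits that left out a library of the compared groups, with edgeR adjusted p from 0.013 to 0.0944.

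Sucrose lowered both factors in Col-0. GNL fell by 2.81 ± 0.44 on the log2 scale (edgeR adjusted p = 0.000143) and GNC fell by 0.93 ± 0.28 (edgeR adjusted p = 0.0125). In gnc gnl the remaining GNL reads fell by 1.23 ± 0.41 (edgeR adjusted p = 0.0325), and in GNLox GNC fell by 1.44 ± 0.29 (edgeR adjusted p = 0.000732). The responses of GNC and GNL were not called as different from those of Col-0 in either line, with edgeR adjusted p = 0.0626 for GNL in GNLox and 0.57 to 0.854 for the other 3 tests. Left-out libraries ended the call of GNL in gnc gnl in 4 of 6 fits and that of GNC in Col-0 in 2 of 6. The share of GNC reads in introns was 1.57% (Wilson interval 1.17% to 2.11%) in Col-0 and 6.91% (5.3% to 8.94%) in gnc gnl without sucrose.

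**Figure D1:**
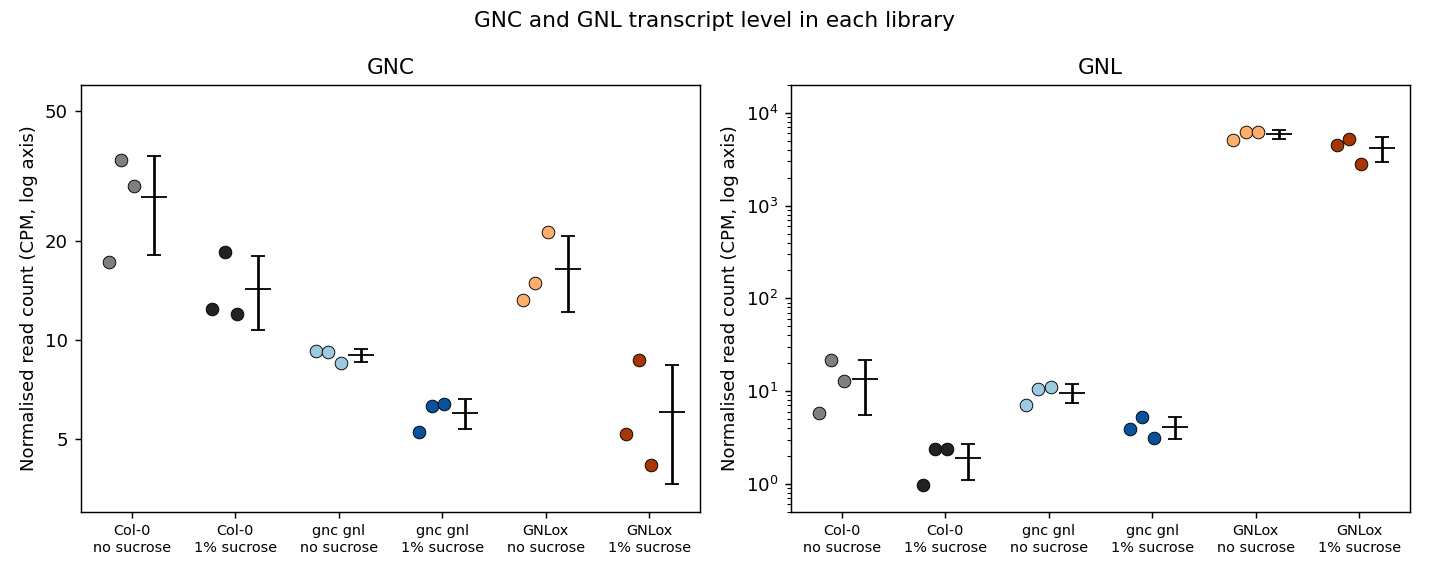
Levels of GNC and GNL in CPM (log axis) for each of the 18 libraries, grouped by genotype and medium, with points for libraries and bars for group means. GNL lies at 5870 and 4190 CPM on average in GNLox, and GNC at 9 and 5.99 CPM in gnc gnl.

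The composition of the libraries differed between and within groups. Nuclear ribosomal RNA took 1% to 25.4% of the gene reads and plastid genes took 0.91% to 23.3%. GNLox replicate 3 without sucrose stood apart, with 23.3% plastid reads and a TMM factor of 0.578. It also had the highest ribosomal RNA share, 25.4%. But gnc gnl replicate 2 without sucrose and Col-0 replicate 1 with sucrose came near it, at 23.15% and 21.96%. The GNLox libraries with sucrose had the lowest mean shares, 2.64% ± 1.7 ribosomal RNA and 1.16% ± 0.34 plastid reads, against 13.6% ± 8.19 and 4.82% ± 1.84 in Col-0 with sucrose. In a principal component analysis, the first component (46.7% of the variance) separated the media and the next (15.4%) separated GNLox from the other genotypes.

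**Figure D2:**
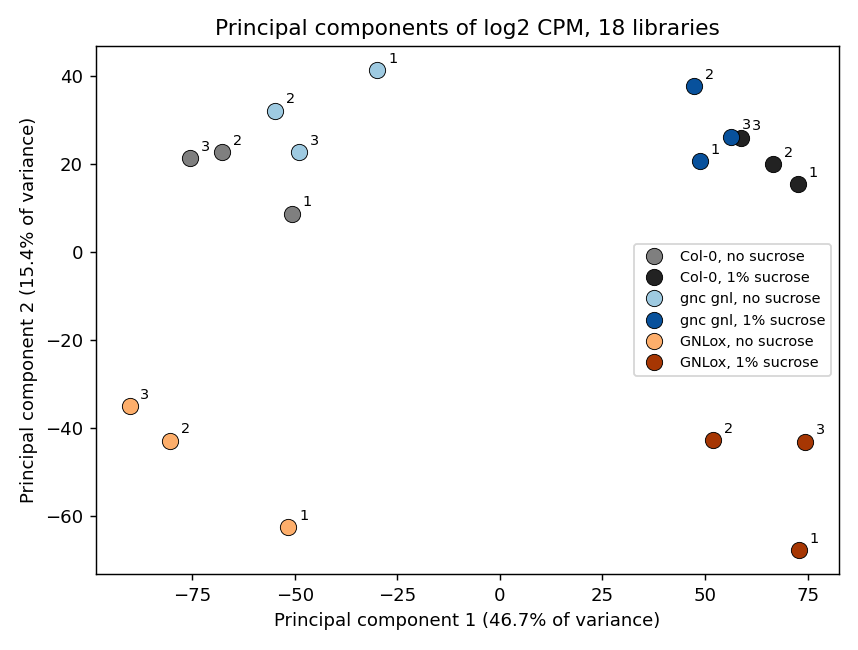
Principal component analysis of log2 CPM, with 1 point per library, a colour for each group of genotype and medium, and the replicate number beside each point. Component 1 holds 46.7% of the variance and parts the media, and component 2 holds 15.4% and parts GNLox from the other lines.

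In Col-0, sucrose lowered genes of carbon starvation, abscisic acid response and light signalling and raised genes of ribosomes, cell division, cell walls, root hairs and glucosinolate synthesis. None of these lists passed with an estimated correlation (adjusted p = 0.0788 to 0.357). Among the largest increases, FOX2 (AT1G26390), a berberine bridge enzyme-like oxidoreductase, rose from 0.695 ± 0.4 to 70.9 ± 8.76 CPM, and DIR14 (AT4G11210), a dirigent protein, rose from 0.0499 ± 0.0162 to 6.05 ± 2.21 CPM. AT5G46890 rose from 0.12 ± 0.105 to 14.4 ± 7.66 CPM. The root iron transporter gene IRT1 (AT4G19690), the root arabinogalactan protein gene AGP30 (AT2G33790) and the extensin gene EXT13 (AT5G35190) had 2, 1 and 2 reads in Col-0 without sucrose and rose by ratios of 646 (counting interval 179 to 5340), 583 (104 to 23100) and 252 (69.4 to 2090). Among the largest decreases, RD29B (AT5G52300), a marker of abscisic acid response, fell from 143 ± 23.4 to 16.5 ± 3.64 CPM, and BCB (AT5G20230), a blue copper-binding protein, fell from 158 ± 30.5 to 25.7 ± 13.2 CPM. XTH25 (AT5G57550), AT4G33467 and AT2G25770 fell, with log2 values of -3.06 ± 0.67, -3.19 ± 0.55 and -3.07 ± 0.27.

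Of 31 carbon starvation genes, 26 fell and 1 rose, both over all genes and adjusted over the list alone (median log2 -0.8, camera adjusted p = 5.28e-08, adjusted p = 0.355 with an estimated correlation). BGLU30 (AT3G60140), a sugar-repressed beta-glucosidase, fell from 1280 ± 102 to 366 ± 15.5 CPM. BCAT2 (AT1G10070), which degrades branched-chain amino acids, fell from 1130 ± 257 to 351 ± 116 CPM and PPDK (AT4G15530), pyruvate orthophosphate dikinase, from 636 ± 74.2 to 266 ± 83.5 CPM. The 1 member that rose was DIN11 (AT3G49620), from 0.671 ± 0.124 to 2.69 ± 0.484 CPM. Of 14 genes of abscisic acid and osmotic stress response, 11 fell and 0 rose by edgeR, with the same counts adjusted over the list alone (median -1.11, camera adjusted p = 0.00134, adjusted p = 0.355 with an estimated correlation). RAB18 (AT5G66400), a dehydrin, fell from 90.5 ± 5.84 to 22.8 ± 12.4 CPM and RD29A (AT5G52310) from 70.4 ± 27.4 to 22.8 ± 5.24 CPM. Of 29 light signalling and greening regulators, 11 fell and 0 rose by edgeR, also adjusted over the list alone (median -0.45, camera adjusted p = 0.00118, adjusted p = 0.355 with an estimated correlation). The photoreceptor gene PHYA (AT1G09570) fell from 1220 ± 240 to 711 ± 112 CPM. HFR1 (AT1G02340), a bHLH factor of light signalling, fell from 166 ± 13.2 to 80.4 ± 1.1 CPM and GLK2 (AT5G44190), a regulator of chloroplast development, from 107 ± 50.7 to 63 ± 11.3 CPM.

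Of 33 cytosolic ribosomal protein genes, 26 rose in Col-0 and 28 did so adjusted over the list alone (median 0.44, camera adjusted p = 2.74e-08, adjusted p = 0.357 with an estimated correlation). RPS6A (AT4G31700) rose from 53.3 ± 3.11 to 110 ± 9.77 CPM and RPL4D (AT5G02870) from 82.6 ± 3.68 to 135 ± 8.56 CPM. Of 19 cell cycle genes, 16 rose, also adjusted over the list alone (median 0.79, camera adjusted p = 9.53e-05, adjusted p = 0.355 with an estimated correlation). They included PCNA1 (AT1G07370), the replication clamp, from 1.54 ± 0.27 to 5.32 ± 1.03 CPM, and MCM2 (AT1G44900), a subunit of the replicative helicase, from 3.64 ± 0.103 to 8 ± 1.33 CPM. Of 24 genes of cell wall loosening and cellulose synthesis, 15 rose and 1 fell, and 16 and 1 did so adjusted over the list alone (median 1.02, camera adjusted p = 9.53e-05, adjusted p = 0.355 with an estimated correlation). The xyloglucan-modifying enzymes XTH17 (AT1G65310) and XTH19 (AT4G30290) rose by log2 2.36 ± 0.41 and 2.43 ± 0.43, and the expansin EXPB3 (AT4G28250) by 2.33 ± 0.21. Of 11 root and root hair markers, 9 rose, and 10 did so adjusted over the list alone (median 2.86, camera adjusted p = 3.41e-05, adjusted p = 0.355 with an estimated correlation). The root hair wall genes PRP3 (AT3G62680), EXPA7 (AT1G12560) and LRX1 (AT1G12040) rose by log2 5.58 ± 0.41, 5.21 ± 0.35 and 4.73 ± 0.39. CASP1 (AT2G36100), a gene of the root endodermis, had a log2 value of 0.24 ± 0.24 and was not called (edgeR adjusted p = 0.413). Of 9 glucosinolate genes, 8 rose, and 9 did so adjusted over the list alone (median 2.5, camera adjusted p = 8.56e-06, adjusted p = 0.0788 with an estimated correlation). CYP79B2 (AT4G39950) and CYP79B3 (AT2G22330), which start indole glucosinolate synthesis, rose from 2.84 ± 0.676 to 54.6 ± 1.39 CPM and from 8.72 ± 0.89 to 49.6 ± 6.86 CPM. Of 16 phenylpropanoid and flavonoid genes, 9 rose and 1 fell, also adjusted over the list alone (median 1.29, camera adjusted p = 0.00534, adjusted p = 0.316 with an estimated correlation). The flavonol regulators MYB12 (AT2G47460) and MYB111 (AT5G49330) rose by log2 2.8 ± 0.73 and 2.62 ± 0.63.

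The other 14 lists did not pass in Col-0. Of 34 auxin genes, 14 rose and 3 fell (also adjusted over the list alone; camera adjusted p = 0.055). IAA5 (AT1G15580) and IAA6 (AT1G52830), early auxin response genes, rose by log2 2.13 ± 0.46 and 1.99 ± 0.4. Of 41 starch and sucrose genes, 13 rose and 5 fell (also adjusted over the list alone; camera adjusted p = 0.293). Sucrose synthase genes went both ways, with SUS3 (AT4G02280) down from 140 ± 3.61 to 56.6 ± 4.96 CPM and SUS4 (AT3G43190) up from 4.65 ± 3.6 to 11.2 ± 0.363 CPM. Of 22 cytokinin and ethylene genes, 10 rose and 3 fell, and 10 and 4 did so adjusted over the list alone (camera adjusted p = 0.211). The response regulator ARR3 (AT1G59940) rose by log2 2.06 ± 0.31. Of 33 brassinosteroid and gibberellin genes, 13 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.648), and GA20OX1 (AT4G25420), a gibberellin biosynthesis gene, rose by log2 1.63 ± 0.36. Of 19 seed oil and glyoxylate genes, 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.086). Isocitrate lyase ICL (AT3G21720) fell from 618 ± 155 to 195 ± 104 CPM and malate synthase MLS (AT5G03860) from 17.2 ± 10.9 to 8.29 ± 1.79 CPM. Of 10 nitrate assimilation genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.139). Nitrite reductase NIR1 (AT2G15620) was at 102 ± 13.2 after 52.5 ± 8.85 CPM.

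Lists of the photosynthetic apparatus did not pass in Col-0. Of 20 light-harvesting antenna genes, 5 rose and none fell by edgeR, and 2 rose adjusted over the list alone (camera adjusted p = 0.139). LHCB1.3 (AT1G29930) rose from 1050 ± 213 to 4120 ± 1340 CPM and LHCB3 (AT5G54270) from 66.5 ± 31.6 to 272 ± 203 CPM. Of 29 tetrapyrrole genes, 2 rose and 2 fell, and 1 and 1 did so adjusted over the list alone (camera adjusted p = 0.748). The ferrochelatase FC1 (AT5G26030) rose by log2 0.63 ± 0.12, and CHLD (AT1G08520), a magnesium chelatase subunit, fell by 0.62 ± 0.21. Of 30 photosystem genes 1 rose and 0 did so adjusted over the list alone (camera adjusted p = 0.961). Of 17 Calvin cycle genes, 2 rose and 2 fell, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.796). Of 16 seed storage genes 1 rose and 2 fell, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.748). Of 9 stomatal genes 1 fell and 0 did so adjusted over the list alone (camera adjusted p = 0.587). Of 11 heat shock and hypoxia genes 2 rose and 1 fell (camera adjusted p = 0.211), and of 6 B-GATA genes 1 rose and 2 fell (camera adjusted p = 0.58), both also adjusted over the list alone. Over all 21903 genes, edgeR called 10903 (5687 higher, 5216 lower). Of the 92 calls of named genes, 69 were kept in each of the 6 fits that left out a library.

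In gnc gnl, IRT1 rose with sucrose from 0.394 ± 0.646 to 22.1 ± 10.1 CPM, AGP30 from 0.0868 ± 0.0891 to 9.58 ± 4.57 CPM and FMO1 (AT1G19250), a monooxygenase of systemic acquired resistance, from 0.0422 ± 0.073 to 8.16 ± 5.44 CPM. The glycine-rich protein gene AT2G05510 rose from 3.4 ± 0.554 to 167 ± 25.9 CPM, and AT3G05727 and AT4G22505 rose by log2 6.01 ± 1.17 and 6.11 ± 0.98. XTH25, BCB, AT2G25770 and RD29B fell, with log2 values of -3.69 ± 0.69, -2.58 ± 0.51, -2.49 ± 0.26 and -2.46 ± 0.4. UGT84A3 (AT4G15490), a sinapate glucosyltransferase, fell from 14.6 ± 3.13 to 2.69 ± 2.83 CPM and AT2G09250 from 8.1 ± 4.75 to 0.259 ± 0.449 CPM.

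Of the carbon starvation genes, 18 of 31 fell and 1 rose in gnc gnl, and 22 fell adjusted over the list alone (median -0.56, camera adjusted p = 2.2e-07, adjusted p = 0.385 with an estimated correlation). BGLU30 fell from 780 ± 346 to 277 ± 39.4 CPM and PPDK from 493 ± 56.5 to 275 ± 92.4 CPM. Of 29 light signalling genes 10 fell, 11 adjusted over the list alone (median -0.37, camera adjusted p = 0.00126, adjusted p = 0.366 with an estimated correlation). HFR1 and the blue light receptor CRY2 (AT1G04400) had log2 values of -0.72 ± 0.14 and -0.54 ± 0.1. Of 14 abscisic acid genes 8 fell and 2 rose, 10 and 3 adjusted over the list alone (median -0.7, camera adjusted p = 0.0174, adjusted p = 0.483 with an estimated correlation). KIN1 (AT5G15960) was one that rose, from 0.804 ± 0.096 to 3.7 ± 1.87 CPM. Ribosomal protein genes rose in 23 of 33 cases, 26 adjusted over the list alone (median 0.35, camera adjusted p = 1.61e-09, adjusted p = 0.385 with an estimated correlation). Cell cycle genes rose in 12 of 19 and fell in 1, 15 and 1 adjusted over the list alone (median 0.57, camera adjusted p = 5.48e-05, adjusted p = 0.343 with an estimated correlation). The cytokinesis gene KN (AT1G08560) rose by log2 1.11 ± 0.22. Cell wall genes rose in 11 of 24 and fell in 1, 13 and 1 adjusted over the list alone (median 0.63, camera adjusted p = 0.00139, adjusted p = 0.483 with an estimated correlation). The expansin EXPA4 (AT2G39700) rose from 34 ± 0.955 to 117 ± 26.6 CPM. Auxin genes rose in 13 of 34 and fell in 1, 19 and 2 adjusted over the list alone (median 0.64, camera adjusted p = 0.00674, adjusted p = 0.588 with an estimated correlation). IAA19 (AT3G15540) rose from 20.1 ± 2.77 to 54.7 ± 15.4 CPM.

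Root markers rose in 7 of 11 in gnc gnl, also adjusted over the list alone (median 1.52, camera adjusted p = 6.52e-05, adjusted p = 0.343 with an estimated correlation). PRP3 rose by log2 3.93 ± 0.38 and COBL9 (AT5G49270) by 3.51 ± 0.41. All 9 tested glucosinolate genes rose, also adjusted over the list alone (median 1.56, camera adjusted p = 1.11e-06, adjusted p = 0.0514 with an estimated correlation). CYP83A1 (AT4G13770), of aliphatic glucosinolate synthesis, was at least 25.4-fold higher. Phenylpropanoid genes rose in 4 of 16 and fell in 1, also adjusted over the list alone (median 0.73, camera adjusted p = 0.00675, adjusted p = 0.316 with an estimated correlation). Phenylalanine ammonia lyase PAL1 (AT2G37040) rose from 55 ± 11.9 to 189 ± 24.7 CPM. Nitrate genes rose in 3 of 10, also adjusted over the list alone (median 0.71, camera adjusted p = 0.0224, adjusted p = 0.316 with an estimated correlation). In all, edgeR called 7063 genes (3925 higher, 3138 lower), and 4626 without gnc gnl replicate 2 without sucrose. Of 73 calls of named genes 53 were kept in each of the 6 fits that left out a library. The nuclear ribosomal RNA share was 17.3% ± 5.69 without sucrose and 7% ± 3.51 with it in this genotype.

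In GNLox, sucrose raised root genes from very low levels and lowered genes of carbon starvation and of seed oil mobilisation, though none of these lists passed with an estimated correlation (adjusted p = 0.278 to 0.363). AT1G48750 was at least 492-fold higher and AGP30 at least 214-fold higher with sucrose, and DIR1 (AT5G48485), a lipid transfer protein of systemic resistance, was at least 257-fold lower. IRT1, AT5G38020, AIR1B (AT4G12545), an auxin-induced root gene, and AT5G38000 had 1 or 2 reads each without sucrose and rose by ratios of 1210 (counting interval 334 to 9990), 716 (128 to 28300), 712 (127 to 28100) and 312 (86.2 to 2580). ASPGB1 (AT3G16150), an asparaginase, fell from 30.8 ± 5.11 to 2.36 ± 0.48 CPM and the transcription factor gene MYB2 (AT2G47190) from 7.24 ± 1.11 to 0.592 ± 0.085 CPM. ECP63 (AT2G36640), a late embryogenesis abundant protein, AT3G53040 and AT1G66870 fell, with log2 values of -4.01 ± 0.87, -3.78 ± 0.77 and -3.87 ± 0.53.

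Carbon starvation genes fell in 28 of 31 cases and rose in 1 in GNLox, also adjusted over the list alone (median -1.34, camera adjusted p = 4.5e-13, adjusted p = 0.278 with an estimated correlation). BGLU30 fell from 1560 ± 285 to 237 ± 22.6 CPM, BCAT2 from 1330 ± 395 to 238 ± 130 CPM and DIN4 (AT3G13450), of branched-chain amino acid breakdown, from 257 ± 51.9 to 60.5 ± 12.8 CPM. Seed oil and glyoxylate genes fell in 13 of 19 and rose in 1, 14 and 1 adjusted over the list alone (median -0.58, camera adjusted p = 0.000246, adjusted p = 0.363 with an estimated correlation). ICL fell from 846 ± 200 to 134 ± 116 CPM, MLS from 26.5 ± 0.715 to 6.96 ± 2.93 CPM and the acyl-CoA oxidase ACX4 (AT3G51840) from 759 ± 78.4 to 326 ± 24 CPM. Light signalling genes fell in 11 of 29, 10 adjusted over the list alone (median -0.4, camera adjusted p = 0.00575, adjusted p = 0.363 with an estimated correlation). PHYA, GLK1 (AT2G20570) and PIF5 (AT3G59060) had log2 values of -1.12 ± 0.24, -1.07 ± 0.31 and -1.02 ± 0.19. Abscisic acid genes fell in 8 of 14 and rose in 2, also adjusted over the list alone (median -0.73, camera adjusted p = 0.0457, adjusted p = 0.52 with an estimated correlation). ABI5 (AT2G36270) fell by 1.58 ± 0.21. The vacuolar invertase BFRUCT4 (AT1G12240) fell from 269 ± 57.5 to 75.8 ± 11 CPM.

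Ribosomal protein genes rose in 30 of 33 in GNLox, also adjusted over the list alone (median 0.65, camera adjusted p = 4.5e-13, adjusted p = 0.363 with an estimated correlation). RPS6A rose from 76 ± 8.82 to 174 ± 15 CPM. Cell cycle genes rose in 16 of 19, 17 adjusted over the list alone (median 1.11, camera adjusted p = 3.54e-06, adjusted p = 0.278 with an estimated correlation). KN rose from 3.94 ± 1.51 to 14.6 ± 0.558 CPM. Cell wall genes rose in 17 of 24 and fell in 3, also adjusted over the list alone (median 0.75, camera adjusted p = 0.00159, adjusted p = 0.463 with an estimated correlation). XTH17 rose from 52.1 ± 25.3 to 259 ± 101 CPM and the expansin EXPA2 (AT5G05290) down from 2.56 ± 2.31 to 0.151 ± 0.136 CPM. Root markers rose in 8 of 11, also adjusted over the list alone (median 2.85, camera adjusted p = 0.00175, adjusted p = 0.363 with an estimated correlation). LRX1 rose by log2 7.57 ± 0.56 and PRP3 by 6.22 ± 0.45. All 9 glucosinolate genes rose, also adjusted over the list alone (median 2.8, camera adjusted p = 1.8e-05, adjusted p = 0.133 with an estimated correlation). CYP83A1 was at least 24.4-fold higher. Phenylpropanoid genes rose in 10 of 16 and fell in 1, also adjusted over the list alone (median 1.27, camera adjusted p = 0.013, adjusted p = 0.278 with an estimated correlation). PAL1 rose from 40.9 ± 10.5 to 196 ± 13.1 CPM. Of the 100 tested plastid genes, 95 fell (median -2.86), and of 60 mitochondrial genes 47 fell (median -2.08). The plastid share of reads was 10.6% ± 11.1 without and 1.16% ± 0.34 with sucrose, and the nuclear ribosomal RNA share was 12.2% ± 11.5 and 2.64% ± 1.7. In all, edgeR called 11997 genes (6276 higher, 5721 lower). Of the 91 calls of named genes, 75 were kept in each fit that left out a library.

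The sucrose responses of the genotypes overlapped. Col-0 and gnc gnl shared 6345 calls in the same direction, 3553 of them higher and 2792 lower where 1019.1 and 747.3 fall together by chance, and 4 in opposite directions. Col-0 and GNLox shared 8600 in the same direction and 56 in opposite ones, and gnc gnl and GNLox shared 5845 and 57. The log2 values correlated across genes with r = 0.804, 0.77 and 0.713 for the 3 pairs, and genes are not independent replicates.

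**Figure D3:**
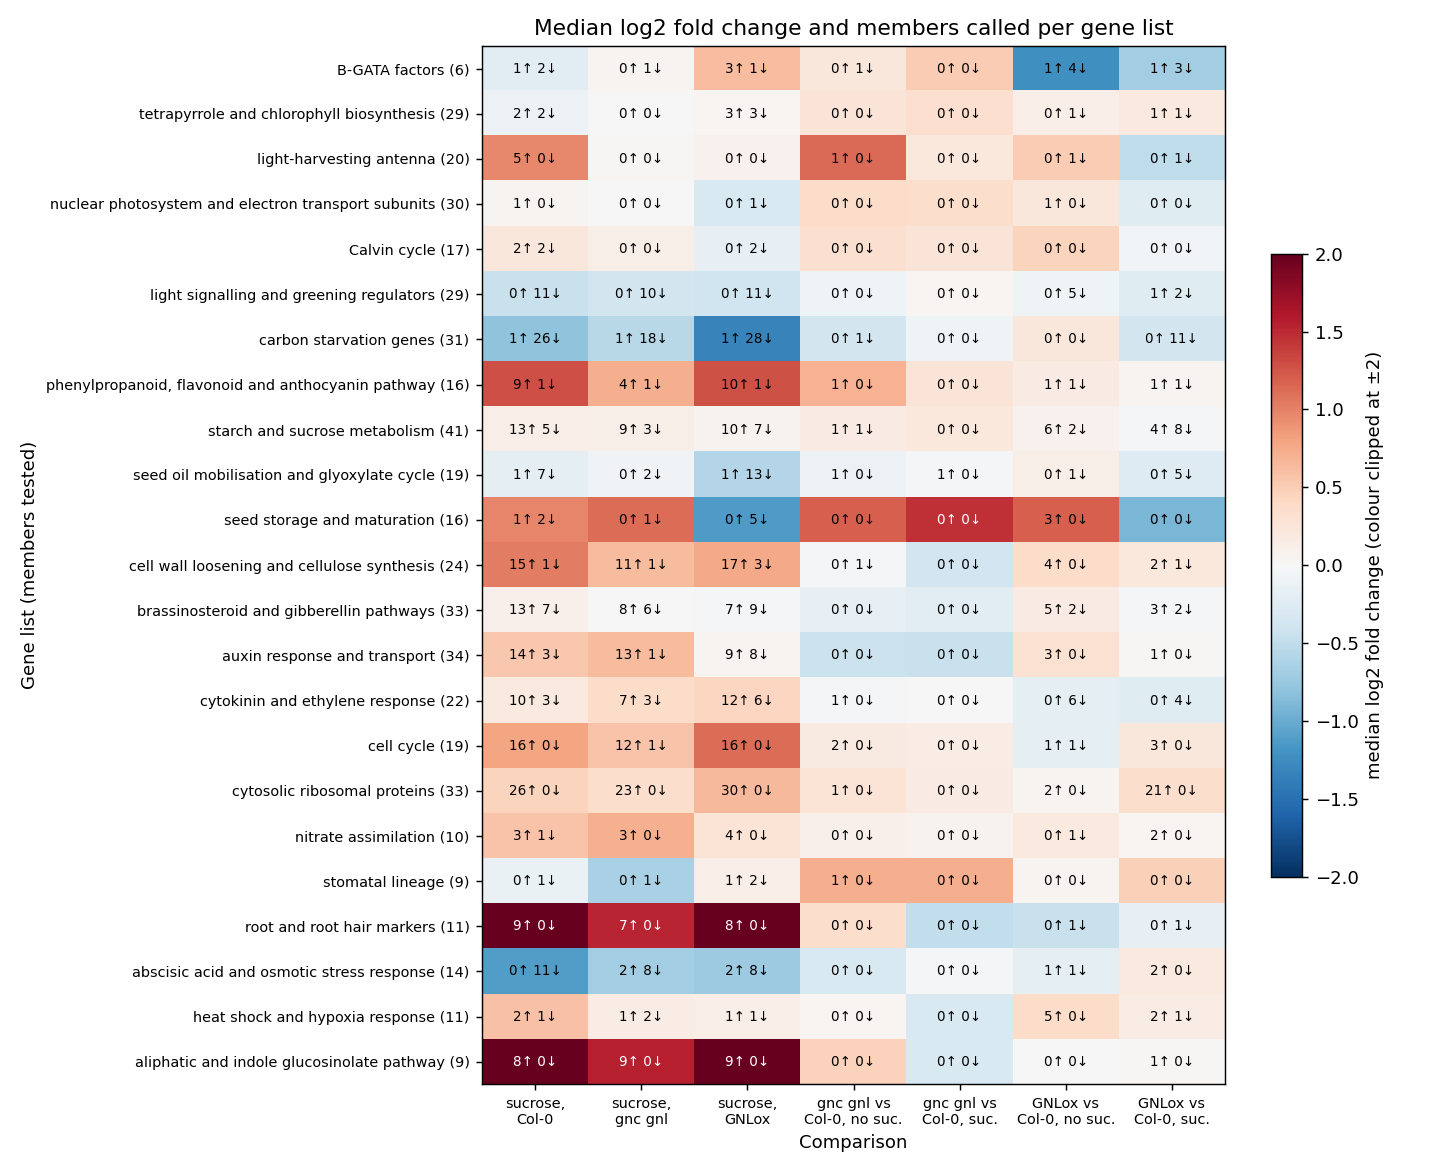
Median log2 ratio of each of the 23 gene lists in the comparisons other than the differences of responses, on a clipped colour scale. Each cell gives the numbers of members called higher and lower by edgeR, and lists that passed by camera are not marked. Carbon starvation genes lie at -0.8, -0.56 and -1.34 with sucrose in Col-0, gnc gnl and GNLox, and root markers at 2.86, 1.52 and 2.85.

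Without sucrose, the genes lower in gnc gnl than in Col-0 included a set of neighbours on chromosome 5. AT1G75945 was at 6.16 ± 0.407 against 0.1 ± 0.099 CPM and AT3G29644 at 11.1 ± 1.26 against 2.53 ± 0.224 CPM. The aquaporin NLM1 (AT4G19030) was at 5.58 ± 2.2 against 0.808 ± 0.27 CPM, the myrosinase TGG2 (AT5G25980) at 7.22 ± 3.53 against 0.534 ± 0.391 CPM, and XTH7 (AT4G37800) at 9.85 ± 7.85 against 1.89 ± 0.776 CPM. LHCB1.2 (AT1G29910), an antenna protein gene with near-identical paralogs, was at 208 ± 259 against 8.58 ± 3.94 CPM, with a spread larger than its mean, and its call was lost in 5 of 6 fits with a library left out. Besides GNC, AT5G57670 was lower, at 11.7 ± 0.755 against 30.1 ± 1.9 CPM, and so was AT4 (AT5G03545), a phosphate starvation RNA, at 3.7 ± 0.486 against 9.88 ± 2.92 CPM. VAR1 (AT5G42270), a thylakoid protease, was at 96.3 ± 2.33 against 246 ± 40.2 CPM. The peroxidase gene PER64 (AT5G42180) was at 38.8 ± 8.04 against 97.5 ± 22.1 CPM and CRP1 (AT5G42310), a factor of plastid RNA processing, at 20.7 ± 0.563 against 47.3 ± 11.8 CPM. These 3 genes lie on chromosome 5 between 16852628 and 16921596, where 11 of 12 neighbouring genes with a mean of at least 2 CPM were lower. This stretch was delimited in these same data as a run of lower genes, so that count describes it and tests nothing.

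Ribosomal protein genes shifted up in gnc gnl by a median of 0.28, with 1 of 33 called (RPS3AA, AT3G04840, log2 0.35 ± 0.08) and 21 adjusted over the list alone (camera adjusted p = 6.44e-16, adjusted p = 0.434 with an estimated correlation). Antenna genes had a median of 1.14, with 1 of 20 higher and 5 adjusted over the list alone (camera adjusted p = 9.54e-05, adjusted p = 0.548 with an estimated correlation). Stomatal genes had a median of 0.73, with 1 of 9 higher and 4 adjusted over the list alone (camera adjusted p = 0.000216, adjusted p = 0.434 with an estimated correlation). The called gene was EPF2 (AT1G34245), a signalling peptide of the early stomatal lineage (log2 2.23 ± 0.46). Phenylpropanoid genes had a median of 0.69, with 1 of 16 higher and 5 adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.399 with an estimated correlation). The called gene was the flavonol synthase gene FLS1 (AT5G08640, log2 2.92 ± 0.66). Cell cycle genes had a median of 0.18, with 2 of 19 higher and 4 adjusted over the list alone (camera adjusted p = 0.00254, adjusted p = 0.434 with an estimated correlation). The called genes were MCM2 (log2 0.87 ± 0.15) and CYCA2;3 (AT1G15570, log2 1.39 ± 0.24). Starch genes had a median of 0.17, with 1 of 41 higher and 1 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00515, adjusted p = 0.436 with an estimated correlation). The ADP-glucose pyrophosphorylase APS1 (AT5G48300) was at 17 ± 4.44 against 6.09 ± 1.45 CPM and the beta-amylase BAM1 (AT3G23920) at 59.7 ± 6.75 against 78 ± 5.58 CPM. Another 4 lists shifted up with no member called by edgeR over all genes: tetrapyrrole genes (median 0.26, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.669 with an estimated correlation), photosystem genes (0.36, 0 adjusted over the list alone, 0.00251 and 0.801), seed storage genes (1.2, 2, 0.00515 and 0.629) and glucosinolate genes (0.46, 3, 0.0467 and 0.434).

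Carbon starvation genes shifted down in gnc gnl without sucrose by a median of -0.37, with 1 of 31 lower (SIP2, AT3G57520, log2 -0.74 ± 0.16) and 4 adjusted over the list alone (camera adjusted p = 2.29e-07, adjusted p = 0.434 with an estimated correlation). Auxin genes had a median of -0.43, with 0 of 34 called by edgeR and 5 lower adjusted over the list alone (camera adjusted p = 2.23e-05, adjusted p = 0.434 with an estimated correlation). Abscisic acid genes had a median of -0.3, with 0 of 14 called either way by edgeR (camera adjusted p = 0.000867, adjusted p = 0.434 with an estimated correlation). Of lists that did not pass, MLS was higher at 49.2 ± 13.8 against 17.2 ± 10.9 CPM, ARR3 at 1.06 ± 0.533 against 0.387 ± 0.058 CPM, and EXPA4 was lower at 34 ± 0.955 against 63.7 ± 6.61 CPM. In all, edgeR called 283 genes (217 higher, 66 lower), and 1040 were called by DESeq2 and 31 in a fit of the 6 compared libraries alone (18 higher, 13 lower). The count was 43, 61 and 25 without Col-0 replicates 1, 2 and 3, and 20, 65 and 908 without gnc gnl replicates 1, 2 and 3. Of 23 calls of named genes, 5 were kept in all 6 of these fits (AT3G29644, NLM1, AT1G75945, AT5G57670 and VAR1).

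With sucrose, MLS was the only member of any list that was called in gnc gnl against Col-0, at 53.6 ± 2.59 against 8.29 ± 1.79 CPM (log2 2.69 ± 0.37, edgeR adjusted p = 0.00487). AT1G75945 (4.85 ± 0.662 against 0.169 ± 0.111 CPM) and AT3G29644 (8.01 ± 0.67 against 1.84 ± 0.262 CPM) were higher. So were the amino acid transporter gene UMAMIT29 (AT4G01430, 19.3 ± 2.61 against 8.14 ± 0.73 CPM), the phosphate status gene SPX1 (AT5G20150, log2 1.08 ± 0.19) and AT3G05945 (log2 1.01 ± 0.17). Of the genes that were lower, PER64 was at 50.8 ± 7.71 against 135 ± 6.39 CPM and SKP1B (AT5G42190), a subunit of ubiquitin ligases, at 70.0 ± 3 against 148 ± 24.3 CPM. UBL5 (AT5G42300), a ubiquitin-like protein, was at 93.3 ± 2.6 against 198 ± 7.24 CPM and AT5G42250 at 28.5 ± 3.99 against 75 ± 7.17 CPM. LBD16 (AT2G42430), a factor of lateral root formation, was at 6.88 ± 1.24 against 15.4 ± 2.41 CPM, and AT5G67488 at 4.81 ± 1.46 against 11.7 ± 3.19 CPM. The first 4 of these lie in the stretch of chromosome 5 given above, and LBD16 lies in a stretch of 5 such neighbours on chromosome 2, of which 4 were called lower,, from 17663353 to 17701417. Of 23 genes called lower with sucrose, 14 lay in these 2 stretches, which were delimited in these same data as runs of lower genes.

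By camera, 10 lists shifted in gnc gnl with sucrose, and edgeR called none of their members over all genes. Upward shifts were found for ribosomal protein genes (median 0.17, 0 adjusted over the list alone, camera adjusted p = 6.63e-08, adjusted p = 0.517 with an estimated correlation), tetrapyrrole genes (0.34, 0, 0.000731 and 0.628), photosystem genes (0.35, 0, 0.00738 and 0.785), stomatal genes (0.72, 4, 0.00753 and 0.517) and starch genes (0.21, 2, 0.0132 and 0.517). Downward shifts were found for auxin genes (median -0.44, 0 adjusted over the list alone, camera adjusted p = 0.000299, adjusted p = 0.517 with an estimated correlation), cell wall genes (-0.38, 0, 0.000395 and 0.517), root markers (-0.49, 0, 0.00193 and 0.517), brassinosteroid and gibberellin genes (-0.22, 0, 0.00217 and 0.517) and heat shock genes (-0.3, 1, 0.0452 and 0.57). In all, edgeR called 35 genes (12 higher, 23 lower), against 341 by DESeq2 and 105 in a fit of the 6 compared libraries alone. The count was 17, 16 and 19 without Col-0 replicates 1, 2 and 3 and 20 without gnc gnl replicate 2. Of 12 calls of named genes, 4 were kept in all 6 such fits (AT3G29644, AT1G75945, UBL5 and SKP1B).

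**Figure D4:**
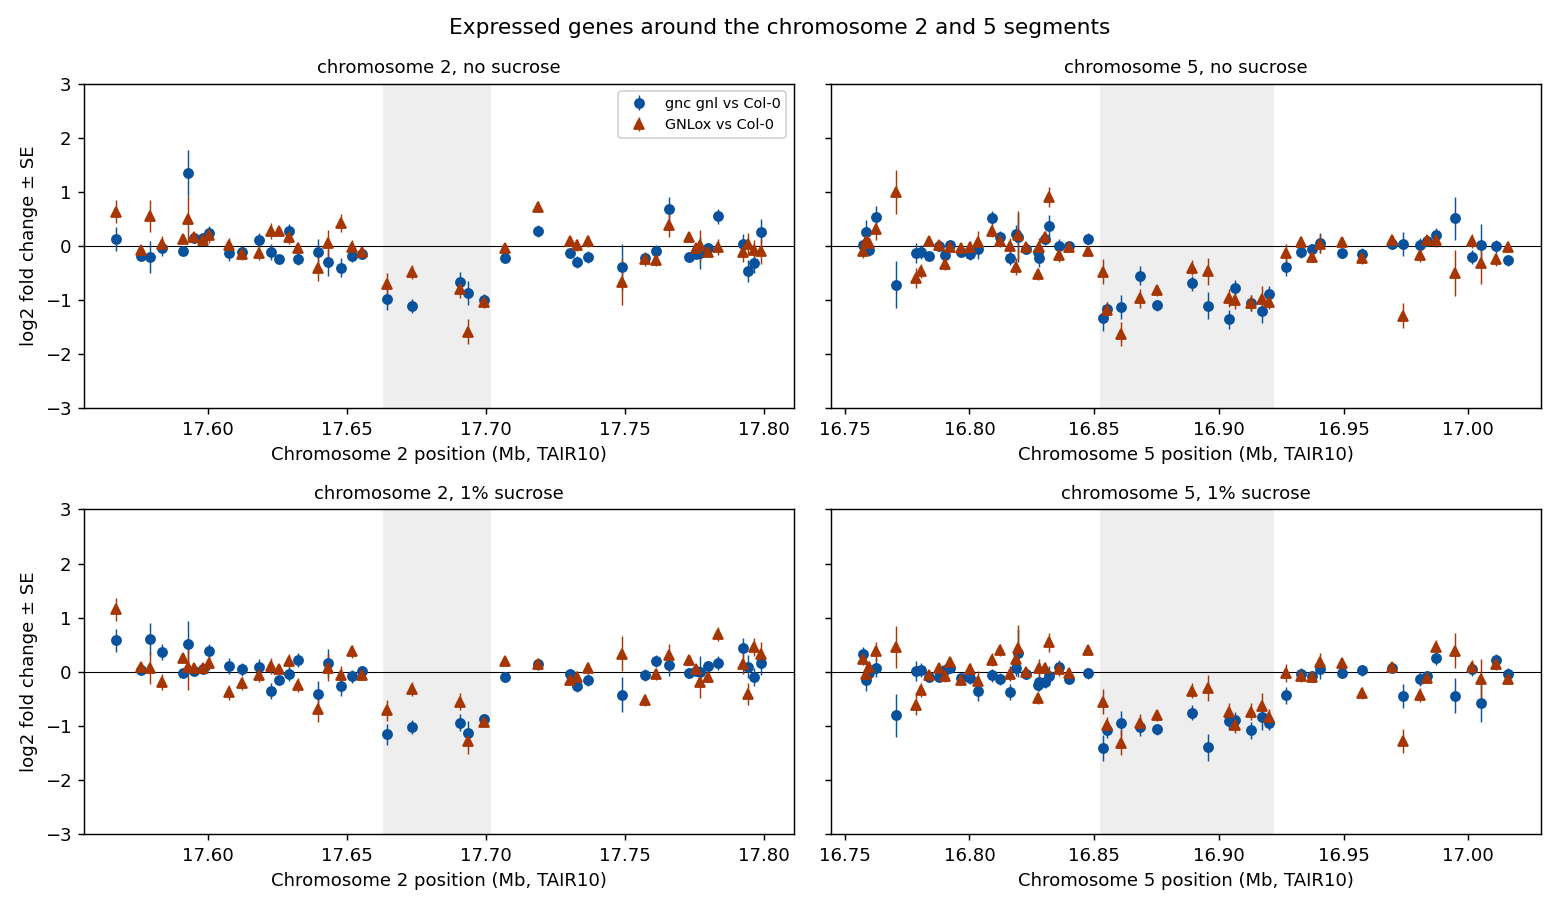
Log2 ratio to Col-0 of genes along the stretches of chromosomes 2 and 5 and their flanks, against position, for gnc gnl and GNLox on both media. The 17 genes inside have medians of -1.06, -1.01, -0.96 and -0.74, and the medians of 20 flanking genes per stretch lie between -0.19 and 0.07. The stretches were delimited in these same data as runs of lower genes, so low medians inside and a change at their ends follow from the choice. Of the flanking genes, 2 to 6 of 20 were called by edgeR in GNLox and 0 in gnc gnl.

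In GNLox without sucrose, the largest increases against Col-0 besides GNL were those of MRD1 (AT1G53480, 4.2 ± 1.44 against 0.0433 ± 0.0749 CPM), AT1G07887 (23.1 ± 1.91 against 0.363 ± 0.027 CPM) and UBC12 (AT3G08700, 5.76 ± 0.755 against 0.0893 ± 0.0511 CPM). They also included ECP63 (4.55 ± 3.39 against 0.128 ± 0.029 CPM) and AT4G21020 (6.83 ± 5.17 against 0.267 ± 0.089 CPM). Among the largest decreases were the suberin genes GPAT5 (AT3G11430, 0.369 ± 0.15 against 4.02 ± 1.36 CPM) and ABCG6 (AT5G13580, 1.11 ± 0.167 against 10.9 ± 2.72 CPM) and CYP705A5 (AT5G47990), of thalianol synthesis (0.592 ± 0.243 against 7.08 ± 2.14 CPM). AT4G33610, AT1G55990 and AT2G22510 were lower by log2 -3.63 ± 0.48, -3.56 ± 0.53 and -3.5 ± 0.53.

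Of the 6 tested B-GATA genes, GNL was higher and 4 were lower in GNLox, 5 adjusted over the list alone (camera adjusted p = 0.046, adjusted p = 0.902 with an estimated correlation). The median was -1.23 while the mean was 0.35, and the test pointed down. GATA16 (AT5G49300), GATA17L (AT4G16141) and GATA17 (AT3G16870) were lower by log2 -2.08 ± 0.4, -1.39 ± 0.21 and -1.37 ± 0.23. Of 22 cytokinin and ethylene genes, 6 were lower, 7 adjusted over the list alone (median -0.2, camera adjusted p = 0.00697, adjusted p = 0.262 with an estimated correlation). ARR7 (AT1G19050) was at 1.11 ± 0.163 against 3.87 ± 0.827 CPM and ARR16 (AT2G40670) at 0.548 ± 0.261 against 1.26 ± 0.423 CPM. Of 24 cell wall genes, 4 were higher, also adjusted over the list alone (median 0.36, camera adjusted p = 0.00697, adjusted p = 0.902 with an estimated correlation). EXPB1 (AT2G20750) was at 8.97 ± 1.91 against 3.42 ± 0.858 CPM and EXPA1 (AT1G69530) at 37.2 ± 5.72 against 22.8 ± 3.5 CPM. Of 34 auxin genes, 3 were higher, 6 adjusted over the list alone (median 0.31, camera adjusted p = 0.0104, adjusted p = 0.902 with an estimated correlation). YUC3 (AT1G04610), of auxin synthesis, and the conjugating enzyme GH3.3 (AT2G23170) rose by log2 1.23 ± 0.26 and 1.11 ± 0.22. Of 11 heat shock and hypoxia genes, 5 were higher, also adjusted over the list alone (median 0.37, camera adjusted p = 0.0251, adjusted p = 0.902 with an estimated correlation). HSP17.4 (AT3G46230) was at 4.6 ± 1.28 against 1.09 ± 0.369 CPM.

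Among lists that did not pass, 5 of 29 light signalling genes were lower in GNLox without sucrose, and 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.075). They included HY5 (AT5G11260), at 26 ± 4.37 against 58.7 ± 20.5 CPM, its relative HYH (AT3G17609), at 1.78 ± 0.264 against 5.96 ± 2.78 CPM, and ELIP1 (AT3G22840), at 2.28 ± 0.377 against 13.4 ± 6.58 CPM. The antenna gene LHCB4.1 (AT5G01530) was lower at 174 ± 44.4 against 644 ± 131 CPM and nitrate reductase NIA2 (AT1G37130) at 207 ± 51.6 against 487 ± 130 CPM. The gibberellin genes PRE1 (AT5G39860) and GA3OX1 (AT1G15550) were higher by log2 1.51 ± 0.24 and 0.89 ± 0.15, and the amylase AMY3 (AT1G69830) by 0.97 ± 0.11. In all, edgeR called 2964 genes (1430 higher, 1534 lower), against 3111 with a block for the replicate number and 1223 in a fit of the 6 compared libraries alone. The count was 1518 and 1824 without Col-0 replicates 2 and 3 and 1782 without GNLox replicate 2. Of 59 calls of named genes, 33 were kept in all 6 fits that left out a library.

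In GNLox with sucrose, PBS3 (AT5G13320), of salicylic acid synthesis, was at 0.549 ± 0.424 against 35.5 ± 6.87 CPM in Col-0 and FOX2 at 2.03 ± 1.81 against 70.9 ± 8.76 CPM. The alternative oxidase gene AOX1D (AT1G32350) was at 0.382 ± 0.084 against 11.1 ± 2.44 CPM and AT3G60415 at 0.404 ± 0.135 against 18.9 ± 2.87 CPM. The receptor kinase gene LECRK31 (AT2G29220) and the ubiquitin ligase gene PUB54 (AT1G01680) were lower by log2 -5.06 ± 0.9 and -4.84 ± 0.82. After GNL, the largest increases were those of AT1G07887 (log2 8.85 ± 0.45), AT2G34700 (17 ± 7.67 against 0.987 ± 0.489 CPM) and AT5G33370 (6.71 ± 2.77 against 0.397 ± 0.201 CPM). They also included the embryogenesis protein gene LEA7 (AT1G52690, 10.2 ± 4.26 against 1.3 ± 0.273 CPM) and the lipid transfer protein gene LTP3 (AT5G59320, 24.1 ± 15.5 against 3.16 ± 1.4 CPM).

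Of 33 ribosomal protein genes, 21 were higher in GNLox with sucrose, 29 adjusted over the list alone (median 0.35, camera adjusted p = 1.97e-11, adjusted p = 0.904 with an estimated correlation). RPS6A was at 174 ± 15 against 110 ± 9.77 CPM. Of 31 carbon starvation genes, 11 were lower, also adjusted over the list alone (median -0.36, camera adjusted p = 1.38e-05, adjusted p = 0.904 with an estimated correlation). PPDK was at 132 ± 39.4 against 266 ± 83.5 CPM and DIN4 at 60.5 ± 12.8 against 103 ± 25.4 CPM. Of 19 seed oil genes, 5 were lower, 7 adjusted over the list alone (median -0.26, camera adjusted p = 0.00144, adjusted p = 0.904 with an estimated correlation). The lipase gene SDP1 (AT5G04040) was at 72.3 ± 5.37 against 101 ± 11.9 CPM. Of 22 cytokinin and ethylene genes, 4 were lower, 5 adjusted over the list alone (median -0.24, camera adjusted p = 0.0202, adjusted p = 0.66 with an estimated correlation). ARR16 and the ethylene synthesis gene ACO4 (AT1G05010) were lower by log2 -1.6 ± 0.35 and -0.96 ± 0.26. Of genes in lists that did not pass, LHCB4.1 was at 113 ± 27.6 against 487 ± 216 CPM and GATA16 at 1.01 ± 0.841 against 3.07 ± 0.184 CPM. RHD6 (AT1G66470), a root hair regulator, was at 1.43 ± 0.384 against 3.39 ± 0.516 CPM and RD29A at 80.9 ± 31.8 against 22.8 ± 5.24 CPM. Of 100 plastid genes 66 were lower (median -2.08) and of 60 mitochondrial genes 51 were lower (median -2.41), in libraries with 2.64% ± 1.7 nuclear ribosomal RNA against 13.6% ± 8.19 in Col-0. In all, edgeR called 4464 genes (2228 higher, 2236 lower), 1645 in a fit of the 6 compared libraries alone and 2144 without GNLox replicate 1. Of 63 calls of named genes, 31 were kept in all 6 fits that left out a library.

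Genes called in both gnc gnl and GNLox went mostly the same way. Without sucrose 67 were shared in the same direction (48 higher and 19 lower, where 14.2 and 4.6 fall together by chance) and 24 in opposite directions (15.2 and 4.3 by chance). With sucrose 20 were shared in the same direction (3 higher and 17 lower, 1.2 and 2.3 by chance) and none by edgeR in opposite directions. Both lines were compared with the same Col-0 libraries, which by itself makes their log2 values agree. These values correlated across genes with r = 0.234 and 0.331, below the means of 0.481 and 0.516 in 20 simulations of unchanged groups. Their covariances, 0.0861 and 0.1052, were 0.0167 and 0.0462 above the simulated means. The highest simulated covariances were 0.081 and 0.0732, so the excess over the simulated range was small without sucrose. The simulations drew each gene independently of the others. Of the genes lower in both lines, 11 without and 10 with sucrose lay in the stretches of chromosomes 2 and 5, which were chosen as lower in both lines. Between media, gnc gnl shared 20 calls in the same direction, and GNLox shared 1367 in the same and 45 in opposite directions.

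No gene was called by edgeR for a sucrose response in gnc gnl different from that in Col-0, with 1656 genes at an unadjusted p under 0.05 and 69 called by DESeq2. By camera, 9 lists shifted. Responses were lower in gnc gnl for root markers (median difference -1.1, adjusted p = 0.000775, adjusted p = 0.638 with an estimated correlation), antenna genes (-0.85, 0.0207 and 0.799), glucosinolate genes (-0.77, 0.000687 and 0.222) and heat shock genes (-0.39, 0.00935 and 0.675). They were also lower for phenylpropanoid genes (-0.35, 0.00935 and 0.294), cell wall genes (-0.29, 0.00488 and 0.799) and ribosomal protein genes (-0.07, 0.0207 and 0.799). They were higher for abscisic acid genes (0.3, camera adjusted p = 0.00293, adjusted p = 0.638 with an estimated correlation) and carbon starvation genes (0.27, 0.000687 and 0.799). Lower and higher refer to the signed log2 response. Abscisic acid and carbon starvation genes fell with sucrose, with medians of -1.11 and -0.8 in Col-0 and -0.7 and -0.56 in gnc gnl. Their higher responses were thus smaller decreases. Adjusted over the list alone, edgeR called 1 glucosinolate gene lower and 0 members of the other 8 lists.

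The sucrose response of GNLox differed from that of Col-0 in 245 genes (167 higher, 78 lower). The balance moved to 74 higher and 114 lower with the compared groups alone, and to 441 and 438 by DESeq2. TRM14 (AT3G61380) rose in both lines, by log2 1.87 in GNLox and 0.41 in Col-0, a difference of 1.46 ± 0.22. The mitochondrial protease gene LON1 (AT5G26860), NRP1 (AT1G74560), a histone chaperone, and AT4G25730 had log2 responses of 0.91, 0.77 and 0.57 in GNLox against 0.16, -0.11 and -0.21 in Col-0. SEC31A (AT1G18830), a coat protein of vesicle transport, had -0.39 against 2.36, and AT4G39830, the subtilase gene SBT3.5 (AT1G32940), GDPD2 (AT5G41080) and AT3G02700 had differences of -1.3 ± 0.18, -0.98 ± 0.14, -1.34 ± 0.2 and -0.52 ± 0.08. CML30 (AT2G15680), a calmodulin-like protein, was at least 104-fold lower with sucrose in GNLox and at a log2 response of -0.75 in Col-0. Each of these 10 had an edgeR adjusted p of 0.0186.

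By camera, 10 lists shifted in GNLox against Col-0. Responses were lower in GNLox for seed storage genes (median difference -2.45, adjusted p = 0.00491, adjusted p = 0.71 with an estimated correlation), antenna genes (-1.1, 0.000802 and 0.71) and carbon starvation genes (-0.64, 2.62e-11 and 0.563). They were also lower for Calvin cycle genes (-0.51, 0.00267 and 0.71), photosystem genes (-0.38, 0.0092 and 0.771), seed oil genes (-0.38, 2.64e-05 and 0.563), heat shock genes (-0.37, 0.00819 and 0.563) and auxin genes (-0.34, 0.00267 and 0.71). They were higher for cell cycle genes (0.35, camera adjusted p = 0.00267, adjusted p = 0.563 with an estimated correlation) and ribosomal protein genes (0.26, 2.29e-10 and 0.563). Lower and higher again refer to the signed log2 response. For carbon starvation genes, which fell with sucrose, the lower response was a larger decrease (median -0.8 in Col-0 and -1.34 in GNLox). No member of these 10 lists was called by edgeR over all genes, and adjusted over the list alone 8 carbon starvation, 2 seed oil, 1 seed storage and 1 heat shock gene were lower. The count of 245 was 879 by DESeq2, 2 without Col-0 replicate 2 or 3 without sucrose, and 60, 30 and 121 without Col-0 replicates 1, 2 and 3 with sucrose. It was 383, 50 and 26 without GNLox replicates 1, 2 and 3 without sucrose, and 44 and 140 without GNLox replicates 1 and 2 with sucrose. Of the 10 named genes AT4G25730 was called in all 12 such fits, and the others lost the call in 1 or 2 fits (edgeR adjusted p up to 0.061).

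The median of a list, its mean and the direction of its test differed in sign in some comparisons. In the sucrose comparisons these were tetrapyrrole, brassinosteroid and gibberellin, antenna and heat shock genes in gnc gnl and GNLox, B-GATA, photosystem and seed storage genes in gnc gnl, and starch and stomatal genes in GNLox, none of which passed. In the comparisons of gnc gnl with Col-0 they were B-GATA, cell wall, cytokinin and nitrate genes without sucrose, seed oil, glucosinolate and abscisic acid genes with sucrose, and starch and seed storage genes in the difference of responses, none of which passed. In the comparisons of GNLox with Col-0 they were B-GATA and nitrate genes on both media, glucosinolate genes without sucrose, brassinosteroid and gibberellin genes with sucrose and tetrapyrrole genes in the difference of responses, and of these the B-GATA list passed without sucrose.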

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

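The tests of GNLox transcripts lower with sucrose, of root share, and of regulation, chance and genes chosen in gnc gnl alone for the chromosome stretches were chosen after their results were seen.

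Genes whose sucrose response differed between GNLox and Col-0 by the test of the difference itself numbered 245. The named ones were TRM14 (log2 difference 1.46), NRP1 (AT1G74560, 0.88), AT4G25730 (0.78), LON1 (0.75), AT3G02700 (-0.52), SBT3.5 (-0.98), AT4G39830 (-1.3), GDPD2 (-1.34), SEC31A (-2.75) and CML30, whose bound is -5.95 because GNLox with sucrose had no read of it. In a fit of the 12 libraries of both genotypes, 188 genes were called, and of 100 labellings with genotype reassigned within medium, the labelled one included, 2 called as many. The highest other labelling called 537 genes, and with Col-0 replicate 2 or 3 without sucrose left out the count of 245 fell to 2, so chance is not fully set aside by this comparison. It set Col-0 replicate 1 and GNLox replicates 1 and 2 without sucrose against Col-0 replicates 2 and 3 and GNLox replicate 3 and kept the sucrose groups whole, so the real genotype difference with sucrose is part of what it tested. The other labellings that kept these groups whole called 24 to 53, and whether the 537 also hold a structure of the samples was not tested.

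Lists also passed with the preset correlation, but none did with an estimated one (adjusted p = 0.563 to 0.771 for GNLox and 0.222 to 0.799 for gnc gnl). Between GNLox and Col-0 the median difference of sucrose responses was -2.45 for seed storage, -1.1 for antenna, -0.64 for carbon starvation, -0.51 for Calvin cycle, -0.38 for photosystem, -0.38 for seed oil, -0.37 for heat shock and -0.34 for auxin genes. It was 0.35 for cell cycle and 0.26 for ribosomal protein genes. Between gnc gnl and Col-0 it was -1.1 for root markers, -0.85 for antenna, -0.77 for glucosinolate, -0.39 for heat shock, -0.35 for phenylpropanoid, -0.29 for cell wall and -0.07 for ribosomal protein genes, and 0.3 for abscisic acid and 0.27 for carbon starvation genes. Single genes did not differ between gnc gnl and Col-0 by edgeR (0 called, 1656 at an unadjusted p under 0.05, 69 by DESeq2). With 0 called by edgeR under the real labels, all 100 labellings of those 12 libraries called at least as many, up to 249, and the comparison decides nothing.

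The share of GNC reads in introns, a column that no comparison used, stood above Col-0 in gnc gnl. Intron reads made up 6.91% of GNC reads without sucrose (52 of 753) and 8.77% with sucrose (60 of 684). In Col-0 they made up 1.57% (43 of 2742) and 1.32% (19 of 1442). Without sucrose the intron counts were thus close, and the higher share there mostly reflects fewer other GNC reads in gnc gnl. In each of the 6 gnc gnl libraries the share was at least 5.36%, and the highest Col-0 library had 1.69%.

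Of the 17 genes in the stretches of chromosomes 2 and 5, which include VAR1, PER64, SKP1B, UBL5 and LBD16, 14 were lower in gnc gnl on each medium, and 14 and 12 were lower in GNLox. In gnc gnl, 0 of 1000 shuffled gene orders held a run as long as that on chromosome 5, while in GNLox it broke into runs of 6 and 5 genes (7 and 108 of 1000), and the chromosome 2 run there had 108. The genes were chosen as lower in both lines. Neither their medians, all at or below -0.74, nor the 0.34 by which the lowest Col-0 library lay above the highest other library therefore decides anything. For the 18 genes of the runs chosen in gnc gnl alone, the GNLox medians were -0.96 and -0.73. The lowest Col-0 library lay 0.34 above the highest GNLox library. Regulation by GNL, if loss and overexpression act in opposite directions, would put GNLox above Col-0, and it lay below. But the same Col-0 libraries served in the choice, which by itself lowers the GNLox ratios by an amount not simulated. Reads of GNL also do not show its loss in gnc gnl, so these values do not decide on regulation by GNL. Regulation through GNC, whose means lay below Col-0 in both lines (called by edgeR in 2 of 4 comparisons), stays open as well. So does a copy-number difference between the Col-0 line and the other lines as a candidate explanation, since DNA copies cannot be read from RNA. Intron reads of these genes, as CPM of all intron reads, were 1810 ± 182 in Col-0, 917 ± 6.9 in gnc gnl and 926 ± 162 in GNLox without sucrose. With sucrose they were 2200 ± 372, 952 ± 97.6 and 1310 ± 274. In the median of log2 CPM centred per gene, GNLox replicate 3 with sucrose, at 0.195, lay between Col-0 (0.538 to 0.679) and the other libraries (-0.43 to -0.178). That library also had the lowest GNL level in GNLox, 2839.25 CPM against 4455.53 and 5283.71 CPM in replicates 1 and 2 with sucrose. A fixed difference alone would not give its value in a uniform sample. But it is 1 library, and whether its seedlings were uniform was not tested.

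Plastid and mitochondrial transcripts were lower in GNLox with sucrose, where nuclear ribosomal RNA was lower as well. Less carry-over of RNA without a poly(A) tail may explain this, though the sources do not state whether poly(A) RNA was selected. Within groups, libraries with more ribosomal RNA held more plastid reads (r = 0.82 over 18 libraries, permutation p = 0.00515, and r = 0.758 without GNLox replicate 3 without sucrose and GNLox replicate 2 with sucrose). Fewer plastid transcripts per cell cannot be told apart from less carry-over, since against Col-0 the plastid share fell by 2.05 ± 0.42 and the ribosomal share fell by 2.4 ± 0.85, a gap of 0.35 ± 0.47.

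Root hair genes were higher with sucrose in the 3 genotypes. If CASP1 follows the share of root tissue, a larger share alone would raise it as much as the root hair genes. The lowest of EXPA7, COBL9, LRX1 and PRP3 lay at least 2.08 above CASP1 on the log2 scale, with 2 standard errors allowed on each side. These genes were picked from the 11 root and root hair markers after their rises were seen, and CASP1 is a single gene. The gap therefore does not show that the root share stayed the same. A larger root share as part of the rise, more root hairs per root, or more transcripts per hair were not tested and stay open.

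For the comparisons of 3 against 3 libraries, the 10 splits cannot give a share under 0.05. Fits of the compared libraries alone called 10557, 7126 and 9092 genes for sucrose in Col-0, gnc gnl and GNLox, with a highest other split of 0 by edgeR each time. They called 31 and 1223 genes for gnc gnl and GNLox without sucrose (highest other 0) and 1645 for GNLox with sucrose (highest other 1). For gnc gnl with sucrose they called 105, and another split called 103. That split set Col-0 replicate 3 and gnc gnl replicates 1 and 2, the libraries with the lowest ribosomal RNA shares (5.59%, 4.76% and 5.19%), against the other 3. In each case 1 split, the labelled one, gave a result as large.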

How the results depend on the processing

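The counts without rRNA genes and the exon reads were chosen after the data were seen. Of 433 results for named genes none reversed under DESeq2, the replicate block, RLE scaling or removal of rRNA genes, and 2, 11, 5 and 0 lost their call. With each library left out in turn, 550 results for named genes lost the call, 2 gained it and 2130 stayed as they were, called or not; for lists 53 lost it, 78 gained it and 787 stayed. All 81 calls of lists were lost with an estimated correlation, 1 each with no filter, a replicate block and no rRNA genes, and 0 with nuclear genes only, and 9, 5 and 1 were gained with no filter, a block and RLE scaling. The scaling alternatives moved the median of all genes by at most 0.021.

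Counts that moved by more than 1.5 times were these, and the cause was not tested except that leaving out libraries or groups leaves fewer samples. With DESeq2 gnc gnl without sucrose went from 283 to 1040 genes (281 of the 283 shared), gnc gnl with sucrose from 35 to 341, the response difference of gnc gnl from 0 by edgeR (1656 at an unadjusted p under 0.05) to 69 and that of GNLox from 245 to 879. Overlaps of gnc gnl and GNLox in opposite directions went from 24 to 113 without sucrose and from 0 by edgeR to 11 with it, and the calls gnc gnl shared between media from 20 to 69. With the compared groups alone the counts were 31 and 105 for gnc gnl and 1223 and 1645 for GNLox, without and with sucrose. With a replicate block gnc gnl without sucrose had 500 and the opposite overlap without sucrose 49.

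With each library left out in turn the counts were 20 to 908 and 16 to 26 for gnc gnl, 1518 to 2542 and 2144 to 4596 for GNLox (without and with sucrose), 4626 to 7104 for sucrose in gnc gnl, 0 to 1 for the response difference of gnc gnl and 2 to 383 for that of GNLox. They were 8639 to 10818 and 10227 to 12366 for sucrose in Col-0 and GNLox, within 1.5 times. For gnc gnl without sucrose the lowest came without gnc gnl replicate 1 and the highest without gnc gnl replicate 3. The response difference of GNLox was 2 without Col-0 replicate 2 or 3 without sucrose. The simulated changes were given only to genes with a mean of at least 2 CPM. At 27362791 gene reads or more per library, 2-fold changes were recovered in 74.6% to 85.1% of these genes in the comparisons of 2 groups and 1.5-fold changes in 34.3% to 43.3%. For response differences these were 64.2% and 10.4% in gnc gnl and 67.2% and 17.9% in GNLox.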

Other observations

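The tests of gene families, intron reads and neighbouring genes in this part were chosen after the results were seen.

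Gene families outside the fixed lists also moved with sucrose. In Col-0, 36 of 53 peroxidase (PER) genes rose and 2 fell (median 1.34, camera adjusted p = 1.14e-06, adjusted p = 0.494 with an estimated correlation). Of laccase (LAC) genes 13 of 14 rose (2.36, 9.59e-06), of fasciclin-like arabinogalactan protein (FLA) genes 13 of 16 (1.89, 1.22e-05), of root hair specific (RHS) genes 8 of 9 (5.09, 0.000171) and of secondary wall (IRX) genes 9 of 10 (1.71, 0.000814), each with an adjusted p of 0.494 with an estimated correlation. Autophagy (ATG) genes went the other way, with 16 of 26 lower and 2 higher (-0.33, 0.00542, and 0.531 with an estimated correlation), and so did peroxisome (PEX) genes, with 17 of 22 lower and 3 higher (-0.43, 0.000175 and 0.494). In gnc gnl and GNLox, 12 and 18 ATG genes fell, 9 and 17 PEX genes fell, and 8 RHS genes rose in each.

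SAUR genes, small auxin-induced genes, were lower in gnc gnl as a group, with a median of -0.65 without sucrose (camera adjusted p = 0.002, adjusted p = 0.945 with an estimated correlation) and -0.68 with it (camera adjusted p = 2.57e-06, adjusted p = 0.628 with an estimated correlation), while edgeR called 0 of 30. In GNLox without sucrose their median was 0.64 and did not pass (camera adjusted p = 0.105), and with sucrose it was -0.04 with 3 of 30 lower (camera adjusted p = 0.72). LAC genes had a median of -0.53 in gnc gnl with sucrose (camera adjusted p = 3.61e-06, adjusted p = 0.628 with an estimated correlation).

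Without sucrose, intron reads made up 8.65% of GNL reads in gnc gnl (Wilson interval 6.91% to 10.8%) and 2.09% in Col-0 (1.45% to 3%). With sucrose they made up 7.68% (5.57% to 10.5%) and 5.03% (2.75% to 9%), and these intervals overlap. The Col-0 share with sucrose rests on 10 of 199 reads. In GNLox the shares were 0.031% without and 0.0355% with sucrose. Of GNC reads in GNLox, intron reads made up 0.609% and 0.51%.

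In GNLox, 6 neighbouring genes from AT4G15660 to AT4G15730 on chromosome 4 were lower, with medians of -0.92 without and -1.17 with sucrose, and 7 of 1000 shuffled gene orders held a run as long. Shuffled orders do not keep related genes side by side. Whether these neighbours are related or share reads was not examined. In gnc gnl, 3 runs of 4 lower neighbours, on chromosomes 1, 3 and 4, held members of the SAUR family such as SAUR62, SAUR26 and SAUR15, and 103 of 1000 shuffled orders held a run as long.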
